A study of Synechocystis sp. PCC 6803 with 22 samples.

How the data were processed

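Gene expression was measured in a glucose-tolerant wild type of the cyanobacterium Synechocystis grown at 6 light intensities, with 22 single-colour Agilent arrays covering 18 cultures, 3 per intensity. The labels describe 3 independent experiments at each intensity, so the replicates are treated as separate cultures. Cy3-labelled total RNA was hybridised. The deposited intensity values are Feature Extraction output, per the file headers (version 10.7.3.1), that was background-subtracted and detrended within each array and not scaled between arrays. Any further processing by the authors is not given in the sources used here.

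The authors' deposited series table holds the same intensity values, rounded. In 21 of its 22 columns 100% of spots lay within 1% of the processed signal of the array. The column of 50 µmol, replicate 3, instead held the pixel SD of the local background in 100% of spots, and was not used. The table's values are on a linear scale with no centring, and they have no ratio direction.

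Each array held 61657 non-control spots for 35270 probes, 10 probes for each of 3527 targets. Of the probes, 26387 had 2 spots and 8883 had 1. The main measure was log2 of the processed signal minus log2 of its 75th percentile over the array's non-control spots. Spots with an outlier flag were left out, spots of a probe were averaged, and probes of a target were averaged. A target was kept if a probe was well above background on every array of every replicate of at least 1 intensity, which left 3265 targets. Where no probe of a target was well above background on any array of a group, a fold is given as a bound. It is taken against the higher of the lowest well-above-background signal and the probe's own. This bound is approximate and applies to the main scaling only. No spot was saturated. Between 62.2% and 89.3% of spots were well above background, and the 75th percentile ran from 106 to 419 between arrays. The number of arrays limits the precision.

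Replicate 2 at 30 and at 1300 µmol was measured on 2 arrays, which were averaged and counted as 1 culture. A second array was titled replicate 3 at both intensities but described as replicate 2, and these 2 arrays were left out.

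The 18 cultures were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, with Benjamini-Hochberg adjustment and calls at an adjusted p under 0.05), in 9 comparisons and a moderated F test over 6 group means. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 read the files, and matplotlib 3.10.9 drew the plots. On simulated data for 300 against 30 µmol over 3265 targets, with 200 changed, 42.4% of 2-fold and 91.2% of 4-fold changes were recovered, and 5.18% of calls were false. The simulated noise was independent between arrays and between targets, with no slide effect. These rates therefore do not cover slide differences in the real data.

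Each replicate number was one slide and one scan (slides 1 to 3), and every intensity was on every slide. A difference between experiments with different replicate numbers cannot be told apart from slide or scan. Below, slide stands for the replicate number. The correlation of same-numbered cultures' deviations from their group means had a median of 0.566 over 45 pairs, and 9 pairs were under 0.1. In 4 of the 9 comparisons every pair was over 0.1, so pairing was treated as a slide batch and the fit with the slide as a block is given beside the counts it moved by over 1.5 times. One culture per intensity per slide allows no test within a slide, so within-slide differences are given as values.

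The targets are named by RefSeq protein IDs, and 0 of 3527 matched the given reference table, so the files and table do not pair them with gene names. Only 11 targets carry a locus tag. The 24 gene lists of 369 locus tags that were fixed before the data were examined matched 0 targets, and their tests were not run. The named-gene rule (the targets with the largest called changes and fixed marker genes) could therefore be applied only to locus-tagged targets. The 2 rising and 2 falling IDs shown were chosen by size after their values were seen. As replacement gene groups, chosen after the target names were seen, targets were sorted by the replicon in their names, and the plasmid names are background knowledge of the records. camera was run with a preset correlation of 0.01 and with an estimated one, with fry beside it, over 45 tests. All used the fit without the slide block. The estimated correlation therefore holds the slide differences, which can raise it, and no blocked version was run.

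Alternatives were the handling of repeat arrays, the slide block, normexp with an offset of 50, quantile, median and detected-probe scaling, the dim-probe filter, the median over probes, the series table, trend and robust moderation, fits on only the compared groups, and leaving out each culture. normexp was run on median signals because the mean signal was not a column used here. The offset of 50 shrinks the changes of targets with low signal. Smaller values and lost calls of dim targets under normexp, and of replicons that hold many, are therefore partly built in.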

Results

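The study asked how Synechocystis, a model cyanobacterium, changes its transcriptome as light rises from 30 to 1300 µmol photons per m² per s, with cultures harvested in mid exponential phase. The 6 intensities were each measured in 3 cultures. Signal is log2 relative to the array's 75th percentile, and limma adjusted p-values are used throughout. Across the 6 intensities, 873 of 3265 targets changed by the moderated F test, and 1543 with the slide as a block. Light intensity accounted for 51.8% of the variance, the replicate number for 27.1% and the residual for 21.1%. The replicate number joins slide, scan and possibly experiment, which cannot be told apart.

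Raising light from 30 to 50 µmol called no target. NP_441764.1, a chromosomal target, was 5.93 ± 0.38 at 30 and 6.25 ± 0.59 at 50 µmol (SD, n = 3). NP_442026.1 was 4.74 ± 0.52 and 4.13 ± 0.38 (SD, n = 3). NP_440316.1 was 1.20 ± 0.15 and 0.26 ± 0.23 (SD, n = 3), with differences of -0.84, -0.99 and -0.99 on the 3 slides, and was not called with the block either (adjusted p = 0.821). limma found 0 targets, and 0 with the slide block. Of 3265 targets, 74 passed an unadjusted p under 0.05 (158 with the block). Both are fewer than the share of 0.05 that chance alone would give.

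At 300 µmol, 333 targets rose and 191 fell against 30 µmol. NP_441764.1 fell by 6.14 on the log2 scale (SE 0.38, adjusted p = 9.85e-08), from 5.93 ± 0.38 to -0.20 ± 0.69 (SD, n = 3). NP_442026.1 fell by 5.00 (SE 0.35, adjusted p = 2.76e-07). Among the 11 locus-tagged targets, whose tag series is used for small plasmids, slr9102 rose by 1.67 (SE 0.38, adjusted p = 0.00778) and slr9003 by 1.42 (SE 0.38, adjusted p = 0.0198), and 9 did not pass the test, while 6 of the 11 were called with the slide block. slr9003 is dim: of its 10 probes, those well above background on every array were 0 at 30, 2 at 300, 0 at 1000 and 0 at 1300 µmol, and on any array 1, 9, 8 and 8. For slr9102 they were 3, 6, 5 and 6 on every array, and 6, 10, 10 and 8 on any. The sizes of both are therefore not exact. Of pSYSA targets, a large plasmid, 1 rose, 9 fell and 66 did not pass, with a median of -0.31 against 0.11 over all targets (camera adjusted p = 1.47e-04). That call was lost with an estimated correlation (adjusted p = 0.870). Relative to all targets the median was -0.43, but -0.14 under normexp on median signals (adjusted p = 0.00832) and -0.24 with only probes above background on every array (adjusted p = 0.0384). Of the 45 replicon tests, camera called 18 with the preset correlation and 0 with an estimated one, and fry called 5. The tests fry called were the locus-tagged group at 300, 1000 and 1300 against 30, and pSYSX at 1100 against 1000 and 1300 against 1100. fry did not call pSYSA at 300 or 1100 against 30 (adjusted p = 0.318 and 0.221). The smallest camera adjusted p with an estimated correlation was 0.870, shared by several replicons, so it does not single out any of them. That correlation was estimated with the slide differences left in.

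With the slide as a block, 604 rose and 362 fell at 300 µmol, and without 300 replicate 3 the count was 285. Under normexp on median signals 252 targets were called, and slr9102 and slr9003 were not (adjusted p = 0.111 and 0.656), nor in the fit of the compared groups alone (0.0794 and 0.0928). The median of all targets lay 0.11 above 30 µmol, and quantile normalization gave 273 rises and 239 falls. slr9003 differed by 2.15, 0.20 and 1.90 on slides 1, 2 and 3, and slr9102 by 2.76, 0.36 and 1.88.

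**Figure D1:**
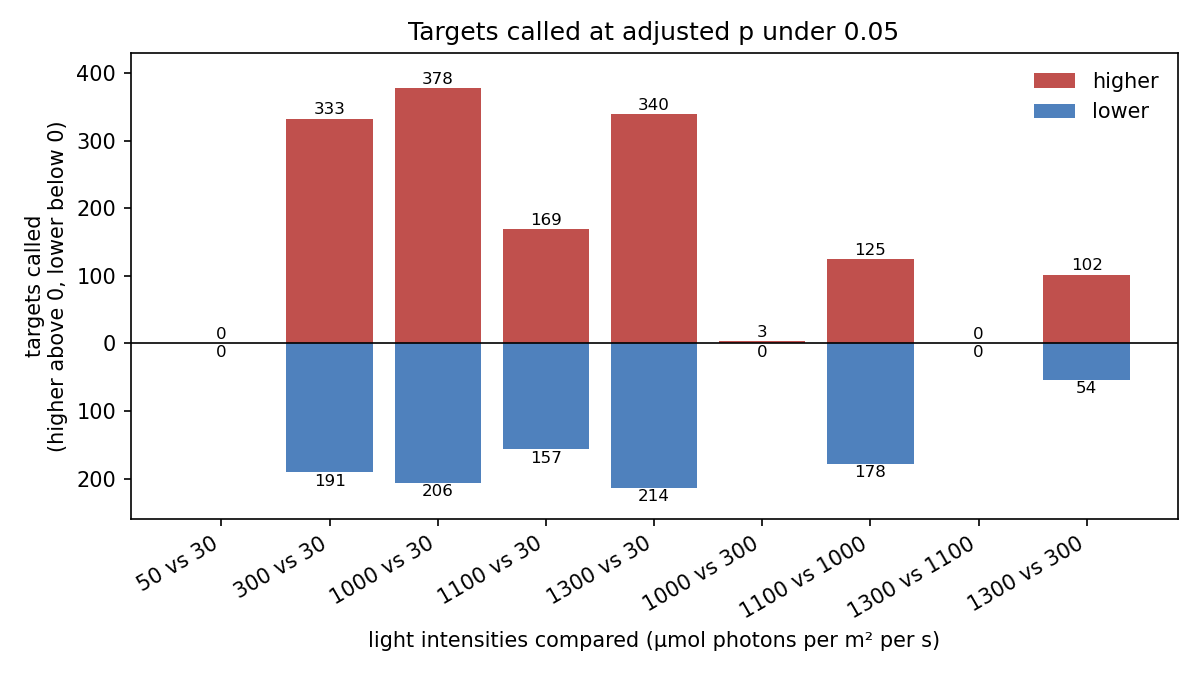
Bars count targets called higher (above 0) or lower (below 0) by limma in each comparison, with the number at each bar. The step from 1000 to 1100 µmol calls 125 higher and 178 lower, the step from 300 to 1000 calls 3 and 0.

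At 1000 µmol, 378 targets rose and 206 fell against 30 µmol. NP_441764.1 fell by 6.52 (SE 0.38, adjusted p = 4.05e-08) and NP_442026.1 fell by 4.78 (SE 0.35, adjusted p = 5.44e-07). slr9102 rose by 1.64 (SE 0.38, adjusted p = 0.00875) and slr9003 by 1.54 (SE 0.38, adjusted p = 0.0134). NP_441239.1 was called at 2.44 (SE 0.63, adjusted p = 0.0162), but at 30 µmol 0 of its 10 probes were well above background on every array and 3 on any, and normexp on median signals gave 0.87. With the block 6 of the 11 locus-tagged targets were called at 1000 µmol, against 2 without it. With the block 713 rose and 379 fell, and without 1000 replicate 1 the count was 291. Under normexp on median signals 223 targets were called, and slr9102, slr9003 and NP_441239.1 were not (adjusted p = 0.0619, 0.360 and 0.164). The fit of the compared groups alone did not call slr9102 or slr9003 (adjusted p = 0.0585 and 0.0814). The median of all targets lay 0.19 above 30 µmol, and median scaling gave 226 rises and 252 falls.

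Between 300 and 1000 µmol, 3 targets rose and none fell. An unadjusted p under 0.05 was reached by 148 of 3265 targets, fewer than the share of 0.05 that chance alone would give. NP_440316.1 rose by 2.24 (SE 0.33, adjusted p = 0.00758), from 0.07 ± 0.65 to 2.31 ± 0.58 (SD, n = 3). slr9102 and slr9003 were not called, nor was any other locus-tagged target. The block gave 10 targets, and the fit of the compared groups alone did not call NP_440316.1 (adjusted p = 0.149). The count was 0 without 300 replicate 1 or without 1000 replicate 3.

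The 300 and 1000 µmol changes against 30 overlapped. Of the targets, 253 rose and 137 fell at both, against 38.6 and 12.1 for independent lists. Both comparisons share the 30 µmol cultures. The fold changes correlated across targets, which are not independent, at r = 0.89, against 0.50 in simulated unchanged groups, and their covariance was 0.466 against 0.0739. The simulated values already include the shared 30 µmol cultures, but with noise independent between arrays and no slide effect. The counts for independent lists do not allow for the sharing, so part of their excess may come from the shared controls. No comparison with separate 30 µmol cultures for each list was run, so the shared part was not removed from the real data.

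From 1000 to 1100 µmol, a small step in light, 125 targets rose and 178 fell. NP_440316.1 rose by 3.42 (SE 0.33, adjusted p = 6.34e-05) to 5.73 ± 0.38 (SD, n = 3), and NP_441239.1 by 3.34 (SE 0.63, adjusted p = 0.00715). Both rose on each slide, NP_440316.1 by 3.60, 2.94 and 3.72 and NP_441239.1 by 2.71, 3.16 and 4.16. slr9102 fell by 1.30 (SE 0.38, adjusted p = 0.0434) and slr9203 fell by 1.05 (SE 0.32, adjusted p = 0.0490), and the block called 3 of the 11. The call of slr9203 was lost in 8 of 14 alternatives and that of slr9102 in 4 of 16, and each in 5 of 6 fits without a culture. Of the 10 slr9203 probes, 1 was well above background on every 1000 µmol array and 0 on every 1100 µmol array (9 and 10 on any array). For slr9102 these were 5 and 6 (10 and 6 on any array). Of pSYSX targets, 13 fell, none rose and 60 did not pass, with a median of -0.47 against -0.15 over all targets (camera adjusted p = 9.04e-04, and 0.870 with an estimated correlation). Relative to all targets it was -0.32, and -0.50 with only probes above background on every array.

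The slide block gave 252 rises and 550 falls for this step, and quantile normalization 166 rises and 132 falls. The 1100 µmol arrays were brighter by a mean of 0.79 (log2 of the 75th percentile), and normexp on median signals left 59 rises and 18 falls, with slr9102 and slr9203 not called (adjusted p = 0.0858 and 0.165). Leaving out 1000 replicate 1, 2 or 3 gave 42, 54 and 55 rises and 4, 18 and 22 falls, and leaving out 1100 replicate 1, 2 or 3 gave 50, 74 and 50 rises and 7, 93 and 19 falls. The median of the 178 falls stayed between -1.35 and -1.13 in these fits, and 4 to 87 of them kept their call. They were chosen with every culture, most of which each fit keeps, so the steady median is largely built in.

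**Figure D2:**
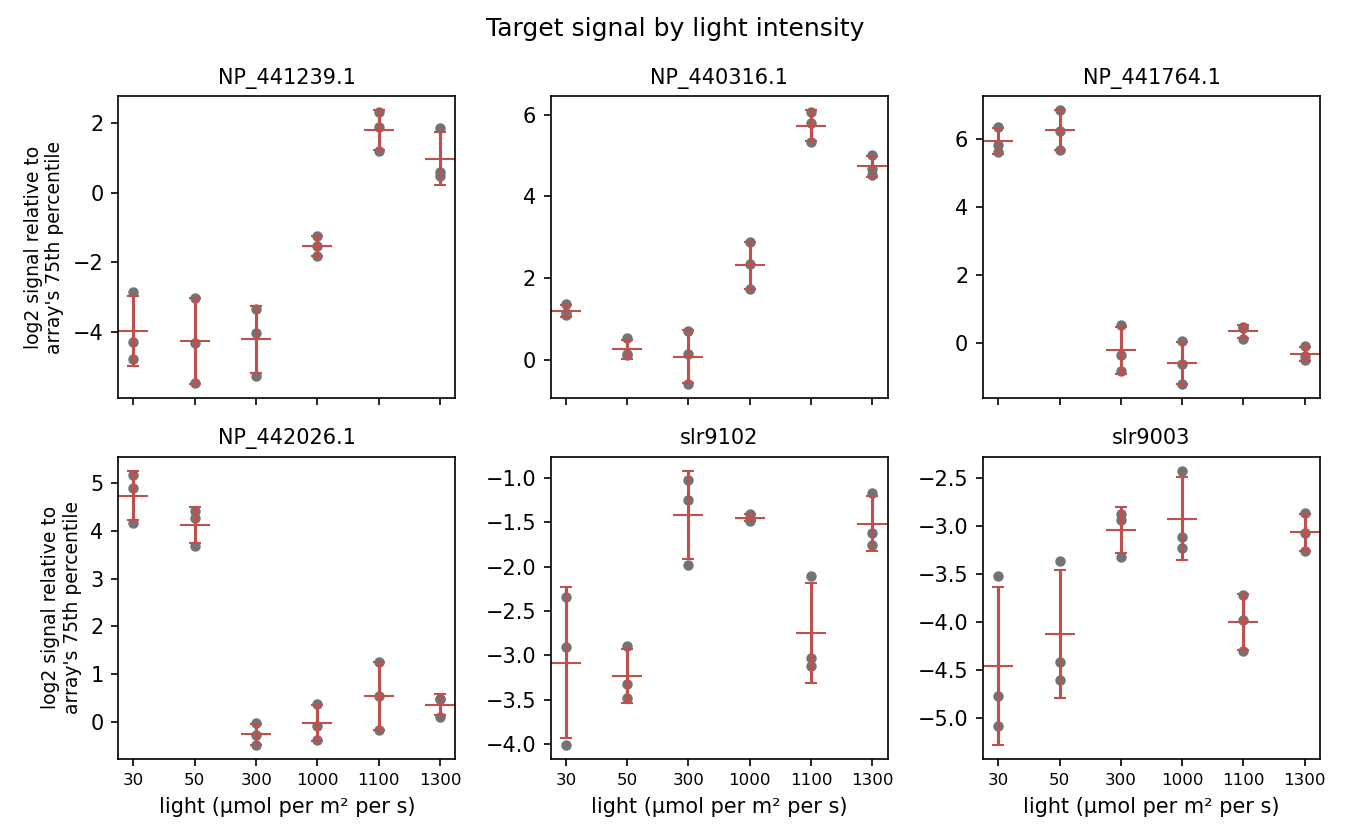
Points are the 3 cultures and red bars the mean with SD of log2 signal at each light intensity, evenly spaced on the axis, for 4 targets shown by ID and for slr9102 and slr9003. NP_440316.1 reaches 5.73 at 1100 µmol, and NP_441764.1 drops from 5.93 at 30 to -0.20 at 300 µmol.

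The step from 300 to 1300 µmol, which shares no array with the step from 1000 to 1100, raised 102 targets and lowered 54. NP_441239.1 was not well above background on any 300 µmol array, so its size is not exact. In the main scaling it was 5.20 higher at 1300 µmol on the log2 scale (limma adjusted p = 1.04e-04), or 5 (32-fold) with the bound. normexp on median signals gave a smaller log2 difference, 2.61 (adjusted p = 3.75e-04), so that bound does not hold across processing. NP_440316.1 rose by 4.66 (SE 0.33, adjusted p = 7.71e-07). Of the 125 targets that rose from 1000 to 1100, 60 also rose from 300 to 1300, against 3.90 for independent lists, and 3 of the 178 that fell also fell, against 2.94. Under the block 198 rose and 147 fell, and 1 of the 11 locus-tagged targets was called, against 0 without it.

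The targets that rose from 30 to 300 µmol were mostly lower at 1100 than at 1000 µmol, with 14.7% of them higher, against 39.3% of all targets, whose median was -0.15 in that step. Above that median lay 22.8% of them. Of these 333 targets, 69 were called lower, against 18.1 for independent lists, and 5 higher. Under normexp on median signals 8 of the 69 were called lower, where the whole step had 18 falls. The 333 targets had a median of -0.44 there, against -0.27 over all targets. Fits without 1 of the 1000 or 1100 µmol cultures kept 1 to 36 of the 69. Of the 191 that fell, 30 were called higher, against 7.31. Across targets the 2 sets of fold changes, from different arrays, correlated at r = -0.48 (-0.40 under normexp on median signals). Simulated unchanged groups gave -0.000486, but their noise was independent between arrays, with no slide or brightness differences. That value was thus fixed by the simulation and is no measure of what such differences give. On slides 1, 2 and 3 the correlation was -0.77, 0.03 and -0.26, strongest on slide 1, where array brightness differed by -1.41 in the first comparison and 1.53 in the second. The 333 risen targets had medians of -0.68, -0.40 and -0.48 on slides 1 to 3, against -0.17, -0.16 and -0.14 over all targets.

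**Figure D3:**
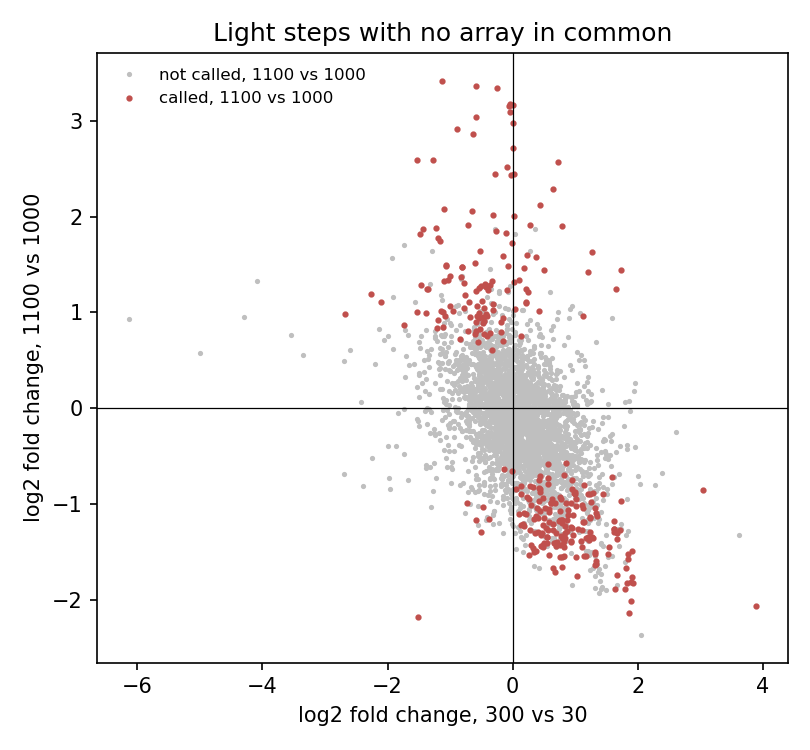
Each point is a target, with its log2 fold change from 30 to 300 µmol (x) and from 1000 to 1100 µmol (y), red where the second was called. The cloud slopes downward with r = -0.48 across targets, and r = -0.77, 0.03 and -0.26 on slides 1 to 3.

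At 1100 µmol, 169 targets rose and 157 fell against 30 µmol. NP_441239.1 rose (adjusted p = 2.12e-05) by a size that is not exact, since none of its probes was well above background on every 30 µmol array: 5.78 in the main scaling and 3.39 under normexp on median signals (adjusted p = 1.02e-05). NP_441764.1 fell by 5.59 (SE 0.38, adjusted p = 1.25e-07). No locus-tagged target was called (2 with the block), and 13 pSYSA targets fell, with a median of -0.50 against -0.01 over all targets (camera adjusted p = 4.77e-05, and 0.870 with an estimated correlation). Relative to all targets it was -0.49, and -0.25 under normexp on median signals. The block gave 297 rises and 284 falls.

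At 1300 µmol, 340 targets rose and 214 fell against 30 µmol. Locus-tagged targets were a median of 0.95 higher, against 0.16 over all targets (camera adjusted p = 0.00107, and 0.870 with an estimated correlation, and 0.79 relative to all targets against 0.30 under normexp on median signals), with 5 called and 6 not, and 9 called with the block. These were slr9102 at 1.57, slr9003 at 1.39, ssl9001 at 1.35, ssr9004 at 1.10 and slr9002 at 0.95, with adjusted p of 0.0102, 0.0201, 0.0103, 0.00921 and 0.0391. NP_441239.1 rose (adjusted p = 7.08e-05) from the same background level, by 4.96 in the main scaling and 2.56 under normexp on median signals (adjusted p = 1.93e-04). NP_442026.1 fell by 4.39 (SE 0.35, adjusted p = 6.18e-07). With the block 611 rose and 355 fell, and under normexp on median signals slr9102, slr9003, ssl9001 and slr9002 were not called (adjusted p = 0.151, 0.534, 0.149 and 0.617). The fit of the compared groups alone called none of the 5 (adjusted p = 0.0814 for slr9102, 0.104 for slr9003, 0.0878 for ssl9001, 0.0960 for ssr9004 and 0.191 for slr9002), and slr9002 was lost in 6 of 14 alternatives. Of the 10 slr9002 probes, 0 were well above background on every 30 µmol array and 2 on every 1300 µmol array (6 and 10 on any). Its size is therefore not exact, and normexp on median signals gave 0.35. Of the 10 ssl9001 probes, 5 were well above background on every 30 µmol array and 10 on every 1300 µmol array. Median scaling gave 239 rises and 288 falls. Without 1300 replicate 1 the count was 307, and without replicate 3 it was 369.

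Between 1100 and 1300 µmol no target was called. NP_440316.1 was 5.73 ± 0.38 at 1100 and 4.73 ± 0.25 at 1300 µmol (SD, n = 3), with an adjusted p of 0.297 in limma. pSYSX targets had a median of 0.57 against 0.11 over all targets, and 0 of 73 passed singly (camera adjusted p = 1.01e-07, and 0.870 with an estimated correlation). Relative to all targets it was 0.46, and 0.27 under normexp on median signals. limma found 0 targets, with or without the block. Of 3265 targets, 408 passed an unadjusted p under 0.05 (777 with the block). Both are more than the share of 0.05 that chance alone would give, but targets are not independent.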

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

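The tests on the repeat arrays and on the step from 1000 to 1100 µmol were chosen after the results were seen, as were the splits for 50 against 30 and 1300 against 1100. The splits within slides were added after the other splits were seen, with their bound set before they were run.

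The repeat array titled 1300 replicate 3, which no comparison used, differed from the first array of that title by an SD of 0.528 over 2548 targets, against 0.117 to 0.235 for the other 3 repeat pairs. After the slide offset was removed, it differed from 1300 replicate 2 by 0.186, within the range of same-RNA arrays, while different cultures differed by 0.329 to 0.473. This is consistent with its description as replicate 2. A noisy hybridisation is argued against by the duplicate-spot SD, at most 0.118 on the 2 arrays against a median of 0.126 over all arrays, and RNA of 1100 replicate 3 by a distance of 0.331. The repeat array titled 30 replicate 3 stays open, at 0.283. The series table column of 50 replicate 3 equalled the background pixel SD in 100% of spots.

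In the step from 1000 to 1100 µmol, which called 303 targets, array brightness rose by 0.79. From 1100 to 1300 it fell back by 0.75, mostly on slide 1 (-1.99, -0.09 and -0.18 on slides 1 to 3). Over all slides 0.392 of the median rise and 0.656 of the median fall were undone there, both above a bound of 0.3. That bound was chosen after the calls were seen and before these shares were computed. Both steps use the 1100 µmol arrays on which these targets were chosen. Some of the undoing, over all slides and on each slide, is therefore built in and is no measure of brightness. On slide 1, the only slide that tests brightness, the rises, of 1.30, moved by -0.16 and the falls, of -1.44, by 1.12. On slides 2 and 3, where brightness hardly moved, the rises moved by -0.40 and -0.845 and the falls by 0.24 and 1.11. The shares over all slides therefore do not stand for slide 1, where the rises were mostly kept and the falls mostly undone. From 300 to 1300 µmol brightness went the other way on slides 1 and 2, by -0.51 and -0.40, where the rises had medians of 1.26 and 0.72 (0.90 over all slides, 96.8% in the same direction), which argues against brightness as their whole cause. The falls kept a median of -0.19 with 74.7% in the same direction, and on slides 1, 2 and 3 their medians were -1.44, -1.0 and -1.21 where brightness rose by 1.53, 0.73 and 0.12. Falls chosen on slides 1 and 2 had a median of -1.18 on slide 3, against -0.14 over all targets, but slide 3 is 1 pair of arrays, so brightness and a response to light cannot be told apart for them. Without 1000 replicate 2, whose duplicate spots were the noisiest (SD 0.393), 72 targets were called, so that array is not the whole cause. The rises and falls then had medians of 1.33 and -1.21, largely built in, since the cultures kept had also served to choose them. A response to light, whose start these comparisons do not place, may underlie the rises as a hypothesis.

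For 3 cultures against 3 there are 10 splits, too few for a share under 0.05. The real counts, with the highest of the other splits, were 524 and 0 for 300 against 30, 584 and 0 for 1000, 326 and 0 for 1100, 554 and 0 for 1300, 3 and 0 for 1000 against 300, 303 and 0 for 1100 against 1000, and 156 and 7 for 1300 against 300. In each, 1 of 10 splits gave as many, and in 50 against 30 and 1300 against 1100, with 0 calls, 10 of 10 did. For the F test 1 of 100 drawn splits (the real one) reached 873, and the highest other gave 561. With the intensities shuffled only within each slide, 1 of 100 (the real one) reached it, and the highest other gave 84 (1543 and 108 with the slide block), so chance assignment of the cultures is argued against for this test.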

How the results depend on the processing

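normexp, the repeat array in place of the first 1300 replicate 3 and the block with the all-array filter were chosen after the data were seen, and the cause of each shift was not tested unless stated. Of 159 counts under alternatives other than leaving out a culture, 135 stayed within 1.5 times the main count. These include 50 against 30 and 1300 against 1100, which gave 0 in the main fit and in every such alternative. No called value of a named target reversed in the fits run. Outside the leave-one-out fits, values of named targets kept their side of the threshold in 519 cases, lost it in 38 and gained it in 9, and in the leave-one-out fits these were 172, 46 and 4. Replicon medians kept it in 245 cases and lost it in 25, all with the preset camera correlation. With an estimated correlation 0 of the 18 replicon calls remained.

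With the replicate block the counts were 966 (300 against 30), 1092 (1000 against 30), 581 (1100 against 30), 966 (1300 against 30), 10 (1000 against 300), 802 (1100 against 1000), 345 (1300 against 300) and 1543 (F test), and the 2 counts of 0 stayed 0. With normexp on median signals they were 252, 223 and 270 (300, 1000 and 1300 against 30), 77 (1100 against 1000), 77 (1300 against 300) and 428 (F test). With only the groups compared, which leaves fewer residual degrees of freedom, they were 94, 204, 164 and 160 (300 to 1300 against 30), 1 (1000 against 300) and 61 (1300 against 300). With the replicate block and only probes above background on every array they were 791 (300 against 30), 6 (1000 against 300), 590 (1100 against 1000) and 264 (1300 against 300).

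Leaving out 1 culture at a time gave 285 to 615 (300 against 30), 291 to 772 (1000), 206 to 367 (1100), 307 to 676 (1300), 0 to 2 (1000 against 300), 46 to 167 (1100 against 1000), 59 to 189 (1300 against 300), 661 to 940 (F test), and 0 to 0 for 50 against 30 and 1300 against 1100. Counts moved by over 1.5 times without 30 replicate 1 (314 at 300, 303 at 1000), 30 replicate 3 (206 at 1100), 300 replicate 1 (307), 300 replicate 3 (285) and 1000 replicates 1, 2 and 3 (291, 373 and 343), 1100 replicate 3 (212), 1300 replicate 1 (307) and 1300 replicate 3 (369), each against 30. For 1100 against 1000 they were 46, 72 and 77 without 1000 replicates 1, 2 and 3, and 57, 167 and 69 without 1100 replicates 1, 2 and 3. For 1300 against 300 they were 96 and 78 without 300 replicates 2 and 3, and 59 without 1300 replicate 1. For 1000 against 300 they were 0 or 1 without 300 replicate 1 or 3 or any 1000 replicate.

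Quantile normalization changed the split to 292 and 272 (1000 against 30), 291 and 297 (1300 against 30) and 166 and 132 (1100 against 1000). The gene lists could not be tested, and normexp on mean signals was not run. Signal over background limits the dim targets, since on 1 array only 62.2% of spots were well above background.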

Other observations

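The tests on neighbouring IDs, except that on array position, and the comparison of replicons were chosen after the data were seen.

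Targets on the 4 large plasmids changed less often than chromosomal ones. By the F test 55 of 293 were called (18.8%), against 814 of 2961 on the chromosome (27.5%, Fisher's exact test p = 0.00111, across targets, which are not independent). The filter on dim probes had kept 293 of 365 plasmid targets and 2961 of 3151 chromosomal ones. Weaker detection of plasmid targets may therefore lower their share, which was not tested. Of the locus-tagged targets 4 of 11 were called (36.4%). Of the targets that rose at both 300 and 1000 µmol, 57 of 253 were also called higher at both 1100 and 1300, and of those that fell, 69 of 137 were called lower at both. The 69 include NP_441764.1 and NP_442026.1.

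Chromosomal targets with neighbouring ID numbers changed together. For 300 against 30 µmol the fold changes of targets 1 apart correlated at r = 0.32 over 2784 pairs (permutation p = 1e-04, the smallest that 10000 shuffles can give), and those 10 apart at 0.01. This was not limited to comparisons with calls. Targets 1 apart also correlated at 0.21 for 50 against 30 and 0.24 for 1300 against 1100 µmol, where no target was called. Their spots were not closer on the array than those of random pairs (ratio of median distances 1), which argues against array position. In the comparison of 1300 with 30 µmol, 97 called targets lay in 24 runs of at least 3 consecutive numbers called the same way, against at most 31 in 100 shuffles. The longest was 14 targets that fell. Whether neighbouring numbers mark genes transcribed together was not tested separately and stays open.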
